A study of Danio rerio with 67 samples.

How the data were processed

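Each sample was 1 sorted cell from the spinal cord of adult Tg(olig2:eGFP) zebrafish. Per the labels' protocols, the cord was transected 5 mm caudal to the junction of brainstem and spinal cord, sham-operated fish kept an intact cord, and pieces of about 0.5 mm just rostral to the lesion, or at the matching level in sham fish, were taken. The pieces of 9 cords per group were dissociated with papain at warm temperature, stained with calcein for living cells and sorted by fluorescence. The lesion group was taken 7 days after the lesion. Group came from the treatment label of each cell, and the plate position from its title. The library kit was not given in the sources used here.

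The authors deposited 1 table of raw read counts per gene, with 1 column per cell and no normalization. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.19.1, aligned to GRCz10 with GSNAP and counted with featureCounts 1.6.2, while the file header names featureCounts 1.6.3. Per the file headers, counting used Ensembl release 87 genes, no strand (-s 0) and a mapping quality of at least 1 (-Q 1), with no option to count reads that map to several places. Reads of a gene and of an antisense partner therefore cannot be told apart, and reads of near-identical copies, such as the hsp70 and MHC class I genes, may be lost, so single values of such genes are uncertain. MHC class I genes also differ between fish, and their counts depend on which alleles the pooled fish carried.

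The table held 32266 genes and 92 spike-in sequences. Spike-ins had 71 reads over all cells (0.000219% of reads) and were left out of totals. Of the gene IDs, 26433 had a symbol in a gene name table, and 2.69% of reads fell on genes with none. That table gives many zebrafish genes the spelling of the human gene, and some symbols stand for several zebrafish genes, so symbols are printed as the table gives them. For shared symbols the values are those of GRIA2 ENSDARG00000052765, GRIN1 ENSDARG00000027828, DLL1 ENSDARG00000010791, HES6 ENSDARG00000019335, IRS2 ENSDARG00000075282, SNAP25 ENSDARG00000020609, STMN1 ENSDARG00000033655, ARPC5 ENSDARG00000019062, EFNA1 ENSDARG00000030326, GNB5 ENSDARG00000055377, SH3BP5L ENSDARG00000019160, ELOVL1 ENSDARG00000103735, FABP7 ENSDARG00000007697 and TAGLN ENSDARG00000045408. Of 1026 symbols on the gene lists, 56 had no match. Coordinates are those of the counted table, on GRCz10, counted from 1.

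Cells needed at least 10000 reads on genes and 500 genes with a read, and all 67 passed. No doublet caller was run on so few cells. Leaving out cells with over 5000 genes, which could hold 2 cells, was added as an alternative. The counts of each gene were summed over the cells of a group and scaled to the summed gene counts as CPM, and the ratio was log2 of lesion over sham after adding 1 CPM to each. Fold values include this addition. Sums carry exact 95% Poisson intervals and shares of cells exact Clopper-Pearson intervals. A gene at 0 in a group was set against 3 counts over that group, and its fold is given as a lower bound by counting alone. Such a bound takes reads as independent and does not allow for differences between cells or fish. Because each group was 1 pool of cells, no test was made, no count of altered genes is given, and no p-value was computed.

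Cells were clustered by Ward linkage on 10 principal components of log2(CPM + 1) of the 1000 genes with the highest variance above the trend. The number of clusters, from 2 to 6, was that with the highest mean silhouette, 3 (silhouette 0.397). With 2 clusters the silhouette was 0.392. A cluster was called oligodendrocyte-like or OPC-like from fixed marker lists, and names rebuilt in this way may differ from those of the authors. A gene counted as detected in a cell at 5 or more reads. Shares of cells and genes per cell were also taken after thinning each cell to 301650 reads, the level of percentile 10 of all cells.

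Before the data were examined, the groups, the cell filter, the ratio, the clustering, 35 gene lists and the rule for named genes were fixed, with the alternatives of scaling, weighting of cells, depth, prior, filters, plate rows, single cells, cell type, clustering and detection. The comparison within oligodendrocyte-like cells, the clustering without the genes that define the clusters, the share of cells by plp1b level and the omission of cells with over 5000 genes were chosen after seeing the data. The rule named, in each direction, the 12 genes (6 in OPC-like cells) with the largest absolute ratio among genes with a proper symbol, at least 20 CPM and detection in at least 40% of cells in the higher group, and the same direction in the mean of per-cell CPM and in plate rows B to E and F to H taken separately. Prefixes of clone names that the rule excludes also removed the crystallin CRYAB, at 103 CPM in sham and 18.2 CPM in lesion cells (log2 ratio -2.44). For each list the 4 most abundant measured members were its examples, and members with a mean of both groups of at least 1 CPM were measured. Other list members named in the text were chosen after their values were seen. A list's median ratio was placed among those of 10000 random lists of the same size, each member replaced by 1 of the 100 genes nearest in mean expression. These percentiles describe these libraries only. Values without the highest cell leave out, for each gene, the cell with its highest CPM in each group.

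The steps were tested on simulated data with 200 of 32266 genes altered 4-fold. In the simulation of all cells the median log2 ratios were 1.87 for raised and -1.96 for lowered genes and 100% had the right direction. For oligodendrocyte-like cells they were 2.11 and -1.97 with 100%, and for OPC-like cells 2.12 and -1.83 with 94%. Of 100 random lists of unaltered genes, 4, 6 and 2 fell outside the central 95% of their random lists in these simulations. Simulated genes varied independently in cells without clusters, so these counts do not carry over to lists whose members vary together.

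Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, statsmodels 0.14.6, python-igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9. R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0 gave the TMM and size factors of the alternatives. The reporter transcript itself was not analysed here, and values of some list members are not reported here.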

Results

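Single cells carrying an olig2:eGFP transgene were sorted from the spinal cord of adult zebrafish 7 days after spinal cord transection or after a sham operation, and their RNA was sequenced cell by cell. In this line the regulatory sequence of olig2, a transcription factor of the oligodendrocyte lineage, drives green fluorescent protein, so the sort takes oligodendrocyte progenitor cells (OPCs), their oligodendrocyte progeny and any other cell in which the transgene is active. The labels name the sorted cells OPCs, and the series title asks how such cells react to a lesion and take part in remyelination. The data hold 35 cells of the sham group and 32 of the lesion group, and each group came from a single pool of 9 cords, so the groups are compared with 1 sample each and without a test. Sham cells had a median of 550763 reads on genes (245408 to 771417), and lesion cells had 431348 (280129 to 620323). The highest correlation of log2 CPM between any 2 cells was 0.838, and each cell was counted once.

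Most sorted cells expressed myelin genes, and their share was lower in the lesion group. Clustering gave 3 groups of cells. An oligodendrocyte-like cluster, led by genes that include plp1b, cd59a and mbpa, held 29 of 35 sham cells (82.9%, 95% interval 66.4% to 93.4%) and 17 of 32 lesion cells (53.1%, 34.7% to 70.9%). An OPC-like cluster, in which 9 of 23 OPC markers, 7 of 28 ependymo-radial glia markers and 6 of 30 neuron markers were detected in at least 50% of the cells, held 5 sham cells (14.3%, 4.81% to 30.3%) and 7 lesion cells (21.9%, 9.28% to 39.97%). The leading genes of this cluster were the glutamate receptor subunits GRIA2 and GRIN1, the guidance molecule SEMA5A and the chemokine CXCL12, and none of its 10 leading genes was on a marker list of any cell type. An unnamed cluster, led by the matrix link protein hapln1a, the Notch ligands dlb and DLL1, the Notch modifier LFNG and the neurogenic factors nhlh2 and EBF2, held 1 sham cell (2.86%, 0.0723% to 14.9%) and 8 lesion cells (25%, 11.5% to 43.4%). In this cluster 10 of 28 ependymo-radial glia markers and 5 of 23 OPC markers were detected in at least 50% of the cells. A cluster that comes almost wholly from 1 group may reflect that pool rather than a cell type.

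**Figure D1:**
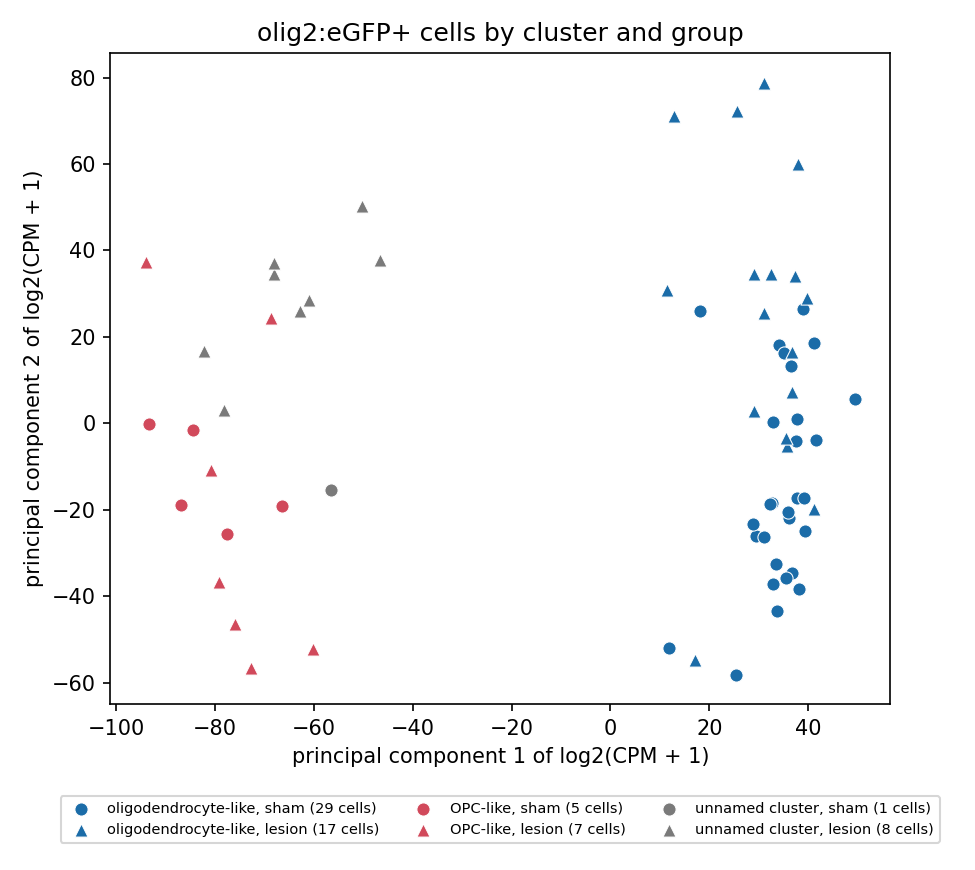
Each point is 1 cell, placed by the first and second principal component of log2(CPM + 1), with colour for the cluster and shape for the group. The 46 oligodendrocyte-like cells lie apart from the others along component 1, and the unnamed cluster holds 8 lesion cells and 1 sham cell.

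With the genes that define the clusters left out, the oligodendrocyte-like share was again 82.9% in sham and 53.1% in lesion cells, while the unnamed cells joined the OPC-like ones. Other genes that vary together with those left out could remain, so this is no independent check. In plate rows B to E the oligodendrocyte-like share was 84.2% of 19 sham cells and 41.2% of 17 lesion cells. In plate rows F to H it was 81.2% of 16 sham cells and 66.7% of 15 lesion cells. The intervals, here and for all other shares and count sums, cover counting error only and say nothing of the spread between fish, and reads without molecular identifiers are not independent molecules.

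Within the unnamed cluster, FOXJ1, a regulator of motile cilia in ependymal cells, was detected in 5 of the 8 lesion cells. ISL1 and MNX1, factors of motor neurons, were detected in the same 3 lesion cells, and SOX2, a factor of neural progenitors, in 5 lesion cells. The summed levels were 401 CPM for FOXJ1, 505 CPM for ISL1, 139 CPM for MNX1 and 386 CPM for SOX2. The single sham cell of this cluster and 2 of the lesion cells had no read of FOXJ1, ISL1 or MNX1. The sham cell had 3293 CPM of SOX2. GPR17, a receptor of committed oligodendrocyte precursors, was at 680 CPM in the sham cell and was detected in 2 of the 8 lesion cells, with a sum of 137 CPM. These were the 2 lesion cells with no read of FOXJ1, ISL1 or MNX1. OLIG2 was detected in all 9 cells of this cluster, at 5457 CPM in the sham cell and 3490.0 CPM in the lesion cells.

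Over all cells, lists of Notch signalling, antigen presentation and interferon, ribosomal protein and cytoskeleton genes were higher in the lesion group, with median log2 ratios of 3.83, 1.38, 0.86 and 1.00, and the list of myelinating oligodendrocyte genes was lower, at -0.50. OLIG2, the gene whose regulatory sequence drives the reporter, lies on chromosome 9 from 32940682 to 32942789 (GRCz10). It was detected in every cell of both groups, at 8201 CPM in sham (95% interval 8160 to 8242) and 7244 CPM in lesion cells (7199 to 7289). Among the genes named by the rule fixed beforehand, which asks for detection in at least 40% of the cells of the higher group, the largest ratios belonged to anxa13l, an annexin (chromosome 2, 10023937 to 10044420), and krt8, a keratin of intermediate filaments (chromosome 23, 10314656 to 10319318). Neither had a read in the 35 sham cells, and they reached 294 CPM (285 to 303) and 282 CPM (273 to 291) in lesion cells. Against the 3 counts that a count of 0 over the sham group allows, anxa13l was at least 1837-fold and krt8 at least 1761-fold higher by counting alone. These bounds do not allow for differences between cells. For each gene, 0 of 35 sham cells still leaves a share of up to 10.0% of cells (95% interval).

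Of the 12 genes that the rule named as higher in lesion cells, isg15 and b2m are on the antigen presentation and interferon list. The ubiquitin-like modifier isg15 stood at 21.2 CPM in sham and 321 CPM in lesion cells (14.5-fold), b2m, the light chain of MHC class I, at 49.4 and 632 CPM (12.5-fold), and the interferon-induced ifi27.1 at 30.4 and 379 CPM (12.1-fold). The b2m transcript was detected in 20% of sham and 75% of lesion cells, and in 16.1% and 72.4% after each cell was thinned to 301650 reads, which left out 4 sham and 3 lesion cells. For anxa13l the shares were 0% (0 of 35 cells, interval to 10.003%) and 40.6% (23.7% to 59.4%), or 0% and 37.9% after thinning. The lesion share was 17.6% in plate rows B to E and 66.7% in rows F to H. On the cytoskeleton list, tubb5, a beta-tubulin, was at 77.9 and 1443 CPM (18.3-fold), while off the lists maptb, which encodes tau, was at 14.5 and 192 CPM (12.5-fold) and CCT8, a subunit of the chaperonin that folds actin and tubulin, at 25.9 and 329 CPM (12.3-fold). HES6, a factor related to the effectors of Notch, had no read in sham cells and 115 CPM in lesion cells, at least 719-fold higher by counting alone. The remaining genes were tmeff1b (6.35 and 276 CPM), MBTPS1, the protease that activates SREBP and ATF6 (4.91 and 117 CPM), and the ESCRT-III subunit chmp4bb (13.2 and 162 CPM). Leaving out 1 cell lowered the log2 ratio of ifi27.1 from 3.597 to as little as 2.18 and that of maptb from 3.64 to as little as 2.75. It raised those of tmeff1b to as much as 6.52, MBTPS1 to 5.98, chmp4bb to 5.797, tubb5 to 4.98, maptb to 4.82, CCT8 to 4.80 and isg15 to 4.52.

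The 12 genes that the rule named as lower in lesion cells were between 11.7-fold and 4.91-fold lower. The tumour necrosis factor receptor family member tnfrsf14 had 122 CPM in sham and 9.51 CPM in lesion cells (11.7-fold lower), tuft1a had 1727 and 167 CPM (10.3-fold lower), and ezh1, a histone H3 methyltransferase of the Polycomb system, had 249 and 29.8 CPM (8.12-fold lower). NFASC, which encodes neurofascin, an adhesion molecule of nodes of Ranvier and paranodes, was at 462 and 80.8 CPM (5.66-fold lower). IRS2, an adaptor of insulin and IGF receptors, was at 188 and 34.97 CPM (5.26-fold lower), the carbonic anhydrase cahz at 1213 and 242 CPM (4.99-fold lower), and the threonine dehydrogenase tdh at 739 and 150 CPM (4.91-fold lower). The MHC class I gene mhc1zda, which is on no list, was at 186 and 27.6 CPM. Its detection was similar, at 45.7% of sham and 43.8% of lesion cells, as were its per-cell medians of 6.98 and 6.10 CPM. The others were ARHGAP18, rnf144ab, RBM38 and aopep. Leaving out 1 cell moved the log2 ratio of tnfrsf14 to as low as -4.18, ezh1 to -3.86, rnf144ab to -3.84, ARHGAP18 to -3.40 and RBM38 to -3.18. In OPC-like cells alone the ratio went the other way for ARHGAP18, mhc1zda and RBM38.

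Among the lists of related genes, the Notch pathway had the highest median over all cells, while in OPC-like cells its median was below 0. Of its 16 measured members 14 were at least 2-fold higher in lesion cells. The median log2 ratio of the list was 3.83 (percentile 100 among 10000 random lists of matched expression), or 5.55 with the 6 members at 0 in 1 group set to their bound. Its most abundant members were dlb (0 and 286 CPM), her4.1 (0.0534 and 201 CPM), her15.1 (19.1 and 177 CPM) and LFNG, which was lower in lesion cells (192 and 135 CPM) but higher without the highest cell of each group (log2 ratio 3.50). The list median without the highest cell of each gene was 4.01. In the 3 lesion cells with ISL1 and MNX1, dlb was at 3674, 2047 and 2916 CPM, against at most 122 CPM in any other cell. Leaving out 1 cell does not show how far the list median rests on these cells. The ligand dlb and LFNG also lead the unnamed cluster, of which 8 of 9 cells are lesion cells. Outside this cluster LFNG averaged only 6.22 CPM per cell, so its sham sum came mostly from the 1 sham cell of the cluster. The antigen presentation and interferon list had 17 of 21 members higher and a median of 1.38 (percentile 99.5), with mhc1uba at 190 and 366 CPM and mhc1zba at 958 and 1215 CPM, while the interferon-induced RSAD2 was lower (154 and 48.7 CPM). Ribosomal protein genes were higher in 75 of 76 cases, with a median of 0.86 (percentile 100), as for RPLP0 (676 and 1659 CPM) and RPS2 (845 and 1707 CPM). Of the actin and tubulin cytoskeleton genes 27 of 35 were higher, with a median of 1.00 (percentile 99.99), although the abundant STMN1 was lower (13038 and 8560 CPM). Extracellular matrix and protease genes had a median of 1.12 (percentile 93.1), with 11 of 21 members at least 2-fold higher and 5 at least 2-fold lower, and it was 0.20 without the highest cell of each gene. Among them were the proteoglycan bcan (202 and 856 CPM) and hapln1a (0.160 and 345 CPM), the gene that leads the unnamed cluster.

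Myelinating oligodendrocyte genes had a median log2 ratio of -0.50 (percentile 1.96), with 14 of 21 members lower in lesion cells, beside the lower share of oligodendrocyte-like cells in that group. Myelin basic protein mbpa was at 31284 and 12089 CPM, the proteolipid gene plp1b at 40592 and 25846 CPM and cd59a at 53192 and 37184 CPM. OPC list genes had a median of -0.16 (percentile 21.6), with 8 of 19 members higher, and the median was 0.15 without the highest cell of each gene. DNA replication genes had a median of -1.12 (percentile 0.16), with 17 of 29 members at least 2-fold lower, among them the replication clamp PCNA (558 and 218 CPM) and the flap endonuclease FEN1 (102 and 21.8 CPM). The median was -0.077 without the highest cell of each gene, 0.18 in plate rows B to E and -3.26 in rows F to H. Mitosis genes had a median of 2.38 (percentile 99.6), or 2.68 with members at 0 set to their bound. The mitosis median was 0.00 without the highest cell of each gene, 3.49 in plate rows B to E and -4.25 in rows F to H. Immediate early genes had a median of -0.0032 (percentile 28.6), or 0.060 without the highest cell of each gene, with JUN at 2219 and 1273 CPM and ATF3 at 349 and 865 CPM. Cholesterol synthesis genes had a median of 0.31 (percentile 55.5), or -1.07 in plate rows F to H, and heat shock genes had one of 0.21 (percentile 72.9), which turned to -0.037 with TMM factors and -0.095 with DESeq2 size factors.

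Markers of other cells were measured beside these genes. Of 30 microglia and macrophage markers 4 were measured, and their sum of 514 CPM in sham and 4851 CPM in lesion cells was almost wholly apoeb (473 and 4787 CPM). No cell of either group had 3 or more markers of microglia, neutrophils, lymphocytes, endothelium or erythrocytes detected. For pericytes 2 lesion cells had 3 or more, for fibroblasts 1 and for skeletal muscle 2, against 0 sham cells for each. Neuron markers had a median log2 ratio of 1.70 (percentile 98.7) with SNAP25 at 110 and 340 CPM. The neuron median was 0.37 (percentile 57.5) in OPC-like cells and -0.18 (percentile 31.4) in oligodendrocyte-like cells. SNAP25 was detected in 12 OPC-like, 4 unnamed and 2 oligodendrocyte-like cells. Ependymo-radial glia markers had a median of 1.31 (percentile 99.96) with FABP7 at 744 and 2294 CPM, but the list summed to 9304 CPM in sham and 9283 CPM in lesion cells. FABP7 was detected in 12 OPC-like, 8 unnamed and 11 oligodendrocyte-like cells, with mean levels of 5706, 3944 and 68.4 CPM. Its ratio over all cells therefore also reflects the different shares of these clusters in the groups. Premyelinating oligodendrocyte markers had a median of -0.16 (percentile 22.6), and Schwann cell markers 1.26 (percentile 88.7) or 0.00 without the highest cell of each gene. Pericyte markers had a median of 2.32 (percentile 98.7), or 4.64 with members at 0 set to their bound and 0.19 without the highest cells. Fibroblast markers had one of 0.043 (percentile 26.8), which turned to -0.12 with TMM factors and -0.28 without the highest cells. Endothelial markers had a median of -1.77 (percentile 1.27), the only measured neutrophil marker, nccrp1, a ratio of -1.01 (percentile 21.5), the only measured erythrocyte marker, cahz, one of -2.32, and skeletal muscle markers a median of 1.19 (percentile 47.6), or 0.39 without the highest cells. Lymphocyte markers had 0 measured members.

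The median ratio of all 13176 tested genes was 0.35, and other scalings moved it by -0.23 (TMM), -0.28 (DESeq2 size factors) and -0.11 (totals without the most abundant genes). Sham cells filled plate columns 1 to 6 and lesion cells columns 7 to 12, so the operation, the pool of fish and the plate columns cannot be told apart.

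**Figure D2:**
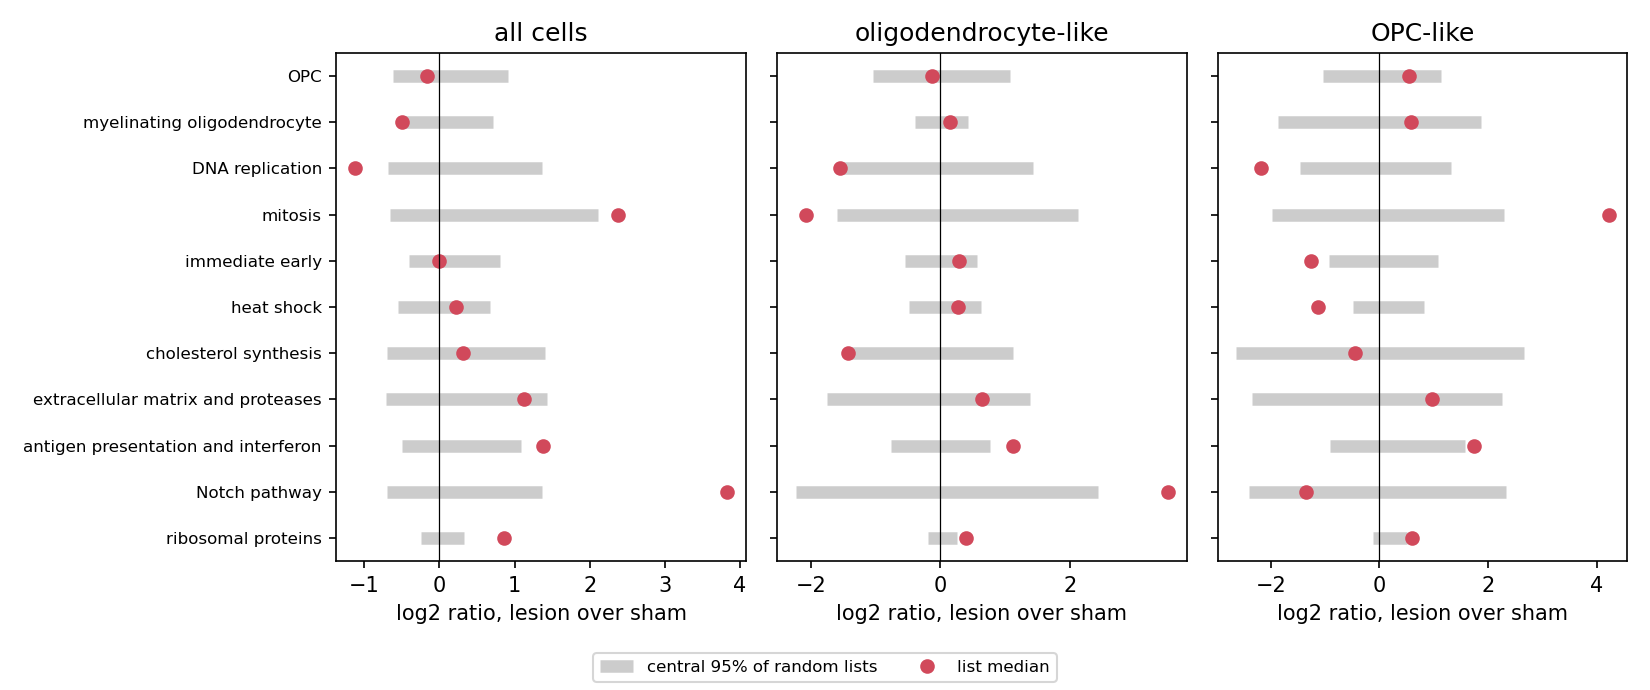
Points are the median log2 ratio of lesion over sham for the measured members of 11 gene lists, in all cells, oligodendrocyte-like cells and OPC-like cells, and grey bars are the central 95% of 10000 random lists of matched expression. Notch and antigen presentation lists lie to the right of the bars in all cells, at 3.83 and 1.38, and DNA replication lies to the left at -1.12, or -0.077 without the highest cell of each gene. The heat shock point in all cells, at 0.21, turns to -0.037 with TMM factors, and the myelinating point in oligodendrocyte-like cells, at 0.15, to -0.015.

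Among oligodendrocyte-like cells, a comparison added after the clusters were seen, apoeb, b2m and the antigen presentation and interferon list (median log2 ratio 1.13, or 0.65 without the highest cell of each gene) were higher in lesion cells. The DNA replication list had a lower median (-1.55, or -1.52 without the highest cells), although its interval included 0. The cholesterol synthesis list also had a lower median (-1.42, or -0.30). The apolipoprotein E gene apoeb (chromosome 16, 24045712 to 24048429), which serves lipid transport, was at 547 CPM (536 to 559) in 29 sham cells and 8634 CPM (8568 to 8701) in 17 lesion cells, 15.7-fold higher. Per cell, its median was 388 CPM in sham cells (0 to 3051) and 4082 CPM in lesion cells (846 to 30933). The second myelin basic protein gene mbpb was at 471 and 3424 CPM (log2 ratio 2.86, or 2.57 without the highest cell), with per-cell medians of 422 CPM (0 to 1293) and 719 CPM (0 to 19194), whereas mbpa was at 36264 and 21750.2 CPM and plp1b at 47055 and 46809 CPM. OLIG2 was at 8728 and 8461 CPM. The gene mbpb was singled out after its values were seen.

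**Figure D3:**
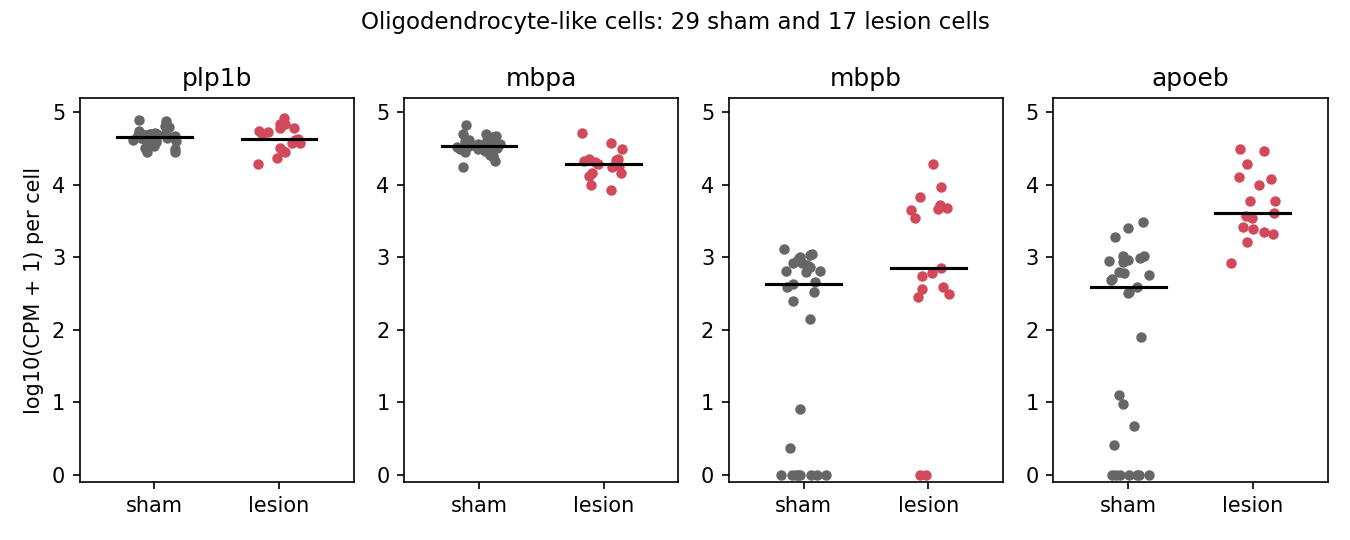
Each point is 1 oligodendrocyte-like cell (29 sham, 17 lesion), on a scale of log10(CPM + 1), and black lines are medians. The apoeb medians were 388 CPM in sham and 4082 CPM in lesion cells, while those of plp1b were 46122 and 43297 CPM.

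Of the 12 genes that the rule named as higher in lesion oligodendrocyte-like cells, 8 had no read in the 29 sham cells: anxa13l (477 CPM in lesion cells), krt8 (299.7 CPM), the membrane protein tspan36 (196 CPM), the glycolytic enzyme HK2 (160.3 CPM), OSTM1 (145 CPM), ssuh2rs1 (145 CPM), ARPC5, a subunit of the actin-branching complex (86.7 CPM), and the axon guidance molecule SEMA3C (71.3 CPM). Against the 3 counts that 0 allows, they were between at least 2568-fold and at least 384-fold higher by counting alone, which does not allow for differences between cells. The b2m gene was at 0.990 and 410 CPM, and ARHGEF10, arpp21 and YIPF5 were at 98.3, 88.7 and 67.1 CPM in lesion cells against 0.309, 0.248 and 0.124 CPM in sham cells. Among the 12 named as lower were the growth factor midkine MDK (ENSDARG00000036036, 275 and 10.1 CPM, 24.9-fold lower), tnfrsf14 (137 and 4.65 CPM, 24.5-fold lower), the ephrin EFNA1 (192 and 13.01 CPM), COX4I2, a subunit of cytochrome c oxidase (441 and 40.5 CPM), the kinase MAP4K5 (324 and 30.1 CPM) and the translation inhibitor PDCD4 (369.8 and 61.1 CPM). These genes also held tuft1a, IRS2, tdh, mhc1zda, ARHGAP18 and ezh1, which, like tnfrsf14, were also named as lower over all cells. Leaving out 1 cell weakened none of these 24 ratios by over 1.5 times. It moved the log2 ratio of MDK to as low as -5.51, tnfrsf14 to -5.33, EFNA1 to -4.61, COX4I2 to -4.36, PDCD4 to -4.11, MAP4K5 and tuft1a to -4.02, ARHGAP18 to -3.58, tdh to -3.43, ezh1 to -3.26 and mhc1zda to -3.21, and that of b2m to as high as 8.28.

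Myelinating oligodendrocyte genes had a median log2 ratio of 0.15 in these cells (percentile 75.3), or -0.015 with TMM factors, with 12 of 20 members higher. Antigen presentation and interferon genes had a median of 1.13 (percentile 99.7), or 0.65 without the highest cell of each gene, and 15 of 18 members were higher. Cholesterol synthesis genes had a median of -1.42 (percentile 2.62), or -0.30 without the highest cell of each gene, with 10 of 18 members at least 2-fold lower, among them insig1, a sterol-regulated brake on the pathway (313 and 91.1 CPM). Of 8 measured Notch pathway genes 7 were at least 2-fold higher (median 3.51, percentile 99.985), among them her15.1 (0.0619 and 129 CPM) and HES6 (0 and 46.1 CPM). The Notch median was 5.81 with members at 0 set to their bound and 0.44 without the highest cell of each gene. Actin and tubulin genes had a median of 0.93 (percentile 99.97), or 0.63 without the highest cells, and ribosomal protein genes one of 0.40 (percentile 99.9), with 63 of 76 higher. Immediate early genes had a median of 0.28 (percentile 86.1), with ATF3 at 219 and 983 CPM. Of the microglia and macrophage markers apoeb was the most abundant, while cd74b was at 10.5 and 21.8 CPM. DNA replication genes had a median of -1.55 (percentile 2.28), or -1.52 without the highest cells. Of 17 members 10 were at least 2-fold lower, among them PCNA (220 and 74.2 CPM). Mitosis genes had a median of -2.07 (percentile 0.61), or -0.044 without the highest cells. Ependymo-radial glia markers had a median of 1.41 (percentile 99.8), or 0.00 without the highest cells, with 9 of 17 members at least 2-fold higher. Of these, SOX2 was at 47.8 and 244 CPM and nes at 170 and 454 CPM, but the list summed to 8994 CPM in sham and 6884 CPM in lesion cells. Schwann cell markers had a median of 1.00 (percentile 87.4), which turned to -0.078 without the highest cells. Endothelial markers had one of -1.65 (percentile 7.85), or -2.15 with members at 0 set to their bound.

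Lesion oligodendrocyte-like cells also had more genes with a read, a median of 2875 against 2154 in sham cells. At 301650 reads per cell the medians were 2802 in 17 lesion cells and 1829 in 26 sham cells, with 3 sham cells left out. The median ratio of the 10302 genes tested in these cells was -0.0064, and TMM factors moved it by -0.15.

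Among OPC-like cells, with 5 sham and 7 lesion cells, ribosomal protein genes were higher in the lesion group (median log2 ratio 0.61, or 0.71 without the highest cell of each gene), as were antigen presentation and interferon genes (1.74, or 0.47). Immediate early genes were lower (-1.27, or -2.89 without the highest cells), as were heat shock genes (-1.14, or -0.22). OLIG2 was at 4694 and 8132 CPM, bcan at 1766 and 3451 CPM, and the proteoglycan cspg5a at 1428 and 326 CPM. The single cells of the groups overlapped for OLIG2, with 1869 to 6658 CPM in sham and 694 to 14069 CPM in lesion cells. They also overlapped for bcan, with 837 to 3134 CPM in sham and 1159 to 8853 CPM in lesion cells. The 6 genes named as higher in lesion cells had no read in sham cells. Of these, isg15 was at 635 CPM, at least 405-fold higher by counting alone. The others were ADAMTSL2 (467 CPM), EIF5A2 (448 CPM), DIP2B (444 CPM), GNB5 (436 CPM) and draxina, an axon guidance molecule (403 CPM). The 6 genes were detected in 3 to 5 of the 7 lesion cells. Leaving out 1 cell brought the log2 ratio of isg15 from 9.31 to 8.32, ADAMTSL2 from 8.87 to 7.34, EIF5A2 from 8.81 to 7.76, DIP2B from 8.80 to 8.07, GNB5 from 8.77 to 7.32 and draxina from 8.66 to 7.98. The 6 named as lower had no read in lesion cells. Of these, cited4b was at 1474 CPM in sham cells, at least 1469-fold lower in lesion cells by counting alone. The others were the hypoxia- and clock-related repressor BHLHE40 (617 CPM), SH3BP5L (443 CPM), the immediate early factor egr1 (426 CPM), STAM2 (410.4 CPM) and the glycogen phosphorylase PYGM (399 CPM). With so few cells, these bounds do not allow for differences between cells. The 6 genes were detected in 2 to 4 of the 5 sham cells. Without 1 of these cells the log2 ratio of cited4b was -6.80 in place of -10.53, SH3BP5L -7.39 in place of -8.79, egr1 -7.32 in place of -8.74, STAM2 -7.83 in place of -8.68 and PYGM -7.98 in place of -8.64.

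Heat shock genes had a median log2 ratio of -1.14 in OPC-like cells (percentile 0.08), or -0.22 without the highest cell of each gene, with 10 of 19 members at least 2-fold lower, as for hsp70l (19132 and 3305 CPM) and hsp70.1 (6059 and 1102 CPM). Immediate early genes had a median of -1.27 (percentile 0.80), or -2.89 without the highest cells, with mcl1a at 5619 and 684 CPM and JUN at 1853 and 603 CPM. DNA replication genes had a median of -2.18 (percentile 0.36), which was 0.00 without the highest cells and 0.84 in plate rows B to E, with 19 of 27 members at least 2-fold lower, among them PCNA (3613 and 795 CPM) and MCM6 (463 and 28.4 CPM). Antigen presentation and interferon genes had a median of 1.74 (percentile 99.0), or 1.40 with members at 0 set to their bound and 0.47 without the highest cells. Ribosomal protein genes had one of 0.61 (percentile 99.6). Mitosis genes had a median of 4.23 (percentile 99.9), or 3.50 with members at 0 set to their bound. The mitosis median was 0.00 without the highest cells and -7.08 in plate rows F to H, and 17 of 27 members were at 0 in 1 group. The OPC list itself had a median of 0.55 (percentile 75.1), and microglia and macrophage markers summed to 318 and 134 CPM. Pericyte markers summed to 6.80 and 457 CPM, mostly TAGLN (0 and 342 CPM, detected in 3 lesion cells). Their median was 4.03 (percentile 99.4), or 3.67 with members at 0 set to their bound and 0.29 without the highest cells. Ependymo-radial glia markers had a median of -0.44 (percentile 12.2). Notch pathway genes had a median of -1.36 (percentile 13.6), or 0.00 without the highest cells and 2.65 in plate rows B to E, with 5 of 9 members at least 2-fold lower and 3 at least 2-fold higher. The level of her15.1 was lower (187 and 72.0 CPM) and that of HES6 higher (0 and 178 CPM). The median ratio of the 9240 genes tested was 0.22, and TMM and DESeq2 size factors moved it by 0.17 and 0.23. With 5 and 7 cells, single cells set several of these list medians, as the values without the highest cells show.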

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

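The tests in this part, all of them about patterns noticed first, were chosen after the result was seen. Spike-in sequences, which no comparison used, had 71 reads over all cells, more than the 3 counts that a count of 0 allows. They were spread over 39 cells with at most 9 in 1 cell, too few to measure the amount of RNA per cell.

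The first pattern is apoeb, at 547 CPM in sham and 8634 CPM in lesion oligodendrocyte-like cells. RNA of microglia or macrophages in the wells would bring their other transcripts, but the 29 other markers on that list summed to 60.3 CPM, or 0.698% of apoeb, with cd74b among the most abundant at 21.8 CPM. Free apoeb RNA spread over the lesion wells would reach OPC-like lesion cells, which had 2.34 CPM or 0.0271% of the level of the oligodendrocyte-like ones, while the lesion cells of the unnamed cluster had 126 CPM. A difference between plate columns or between the 2 pools of fish stays open, because 0 plate columns hold cells of both groups. A response of oligodendrocytes to the lesion may be the source, but it cannot be told apart from the pool.

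The second pattern is the larger number of genes per lesion oligodendrocyte-like cell. It did not come from a difference in reads, since the ratio of the medians was 1.33 as sequenced and 1.53 at 1 fixed number of reads. An OPC-like cell in the same well would bring its abundant transcripts, but genes detected in all 5 sham OPC-like cells and in 0, at most 1 or at most 2 sham oligodendrocyte-like cells (17, 33 and 43 genes) stayed under 10% of their lesion OPC-like median in at least 93.3% of the 15 lesion cells with more genes than the sham median, which argues against it as the cause in most of these cells. In lesion oligodendrocyte-like cells cspg5a and bcan were at 0 and 14.7 CPM, against 326 and 3451 CPM in lesion OPC-like cells, while the highest cell reached 13.1% for the chosen genes, and for OPC list genes, which were tested first and which some oligodendrocytes express, 11 cells (73.3%) were under 10% and the highest reached 17.4%, so a small admixture in single cells stays open. A cell of the unnamed cluster in the same well was not tested. Among lesion oligodendrocyte-like cells, 1 had hapln1a at 91.4 CPM and FOXJ1 at 30.5 CPM, and the others had at most 2.29 and 9.16 CPM. The lesion cells of the unnamed cluster summed to 1488 and 401 CPM. A pair of oligodendrocytes in 1 well could raise the number of genes too, since with at most 9 spike-in reads in a cell the amount of RNA could not be measured. The lesion itself may alter the number of genes, which was not tested.

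The third pattern is myelin reads in lesion cells outside the oligodendrocyte-like cluster, where 6 of 15 cells had 20 or more reads of mbpa and plp1b in sum. In 3 of them the ratio of mbpa to plp1b lay within that of lesion oligodendrocyte-like cells, so RNA carried over from other wells and expression of their own cannot be told apart. In the other 3, all from the unnamed cluster, the log2 ratio was at least 3.69, against at most 0.47 in lesion oligodendrocyte-like cells, which argues against such carry-over. With only 49, 3 and 4 reads of plp1b in these cells, the counting limits still leave a log2 ratio of at least 2.75. A candidate explanation is that these cells transcribe mbpa ahead of plp1b, but this was not tested. Only lesion cells were counted here. Among sham OPC-like cells, 1 also had both transcripts detected, with plp1b at 146 CPM and mbpa at 135 CPM. Myelin reads outside the oligodendrocyte-like cluster were therefore not particular to the lesion group.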

How the results depend on the processing

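Alternatives within oligodendrocyte-like cells, the clustering without the genes that define the clusters, the share by plp1b level and the omission of cells of over 5000 genes were chosen after seeing the data. Of the alternative medians of 8 lists 19 had the opposite sign to the main median, and 3 of these, called reversed, were of lists whose interval excluded 0. Of all 116 stayed within the interval of the main median and 17 left it without being reversed. Of those of single named genes 497 stayed within the counting interval, 369 left it and 3 were reversed. With TMM factors the OPC median was -0.41 and the myelinating median -0.75, and with DESeq2 size factors they were -0.47 and -0.81. In plate rows B to E the myelinating median was -0.92, the mitosis median 3.49 and the DNA replication median 0.18, with its direction reversed. In rows F to H DNA replication was at -3.26, cholesterol synthesis at -1.07 and mitosis at -4.25, reversed. Without the highest cell of each gene DNA replication was at -0.077 and mitosis at 0.00, and with a prior of 0.1 CPM mitosis was at 3.33. In OPC-like cells alone the medians were 0.58 (myelinating), -2.18 (DNA replication), 4.23 (mitosis) and -1.27 (immediate early), and the ratios of ARHGAP18 (2.60), mhc1zda (1.17) and RBM38 (1.59) were reversed. In oligodendrocyte-like cells alone they were 0.15 (myelinating), -1.42 (cholesterol synthesis) and -2.07 (mitosis, reversed). With 1 fewer cluster, 500 genes, Leiden clustering or without the genes that define the clusters, the unnamed cluster held 0% of sham and 0% of lesion cells and the OPC-like share of lesion cells was 46.9%. The share of lesion cells with anxa13l was 17.6% in rows B to E and 66.7% in rows F to H. The cause was not tested for any of these. All 41 alternative counts of named genes were within 1.5 times the main count. The rule had picked the largest ratios and asked for the same direction in the mean of per-cell CPM and in both sets of plate rows. These settings are among the alternatives, so the result was largely fixed in advance and says little of stability. Neither alternative cell filter removed a cell, so they say nothing of stability. The share of oligodendrocyte-like cells was 82.9% and 53.1% in every clustering tried except without cells of over 5000 genes, where it was 82.4% and 53.3%. The share of cells with at least 10000 CPM of plp1b was also 82.9% and 53.1%, but plp1b leads that cluster, so it is no independent check. Counting intervals of the sums were narrow, so the number of cells and the single pool per group set the precision. No paired analysis was possible because each group was 1 pool and no number ties a sham cell to a lesion cell.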

Other observations

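The comparison within oligodendrocyte-like cells was added after the clusters were seen. Further gene lists were compared over all retained cells, as median log2 ratios of lesion over sham with their percentile among random lists. Genes that answer FGF and ERK signalling had a median of 1.05 (percentile 91.1), or 0.57 without the highest cell of each gene and -0.27 in plate rows F to H, with SPRED1 at 43.2 and 197 CPM and the AP-1 factor FOSL1 at 26.4 and 247 CPM. Targets of BMP signalling had a median of -0.58 (percentile 6.77), with 10 of 13 members lower, among them the differentiation inhibitor ID3 (561 and 188 CPM), while ID2 was higher (29.5 and 84.0 CPM). In OPC-like cells the FGF and ERK median was -1.68 (percentile 5.88), or -1.95 without the highest cells, and the BMP median was -3.91 (percentile 0.70), or -0.74 without the highest cells. Wnt targets were at -0.41 (percentile 17.1) and Hedgehog targets at 1.73 (percentile 66.5), with GLI3, detected in 1 lesion cell, at 0 and 16.5 CPM, and the Hedgehog median was 0.053 without the highest cells. Cytokine and chemokine genes were at 1.41 (percentile 95.3), or 0.029 without the highest cells, and the galectin lgals2a stood at 0.0534 CPM in sham and 279 CPM in lesion cells.

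Over all retained cells, translation factors and nucleolar genes had a median of 0.47 (percentile 79.4), and the elongation factors eef1a1l1 (2117 and 5315 CPM) and eef2b (694 and 2052 CPM) were higher in lesion cells. Nuclear genes of oxidative phosphorylation were at 0.38 (percentile 93.1), and mitochondrially encoded genes at 0.24 (percentile 73.6), which turned to -0.016 with TMM factors. Glycolysis genes were at 0.49 (percentile 85.7), fatty acid and sphingolipid synthesis genes at -0.076 (percentile 21.8), and ion channel and transmitter receptor genes at 1.18 (percentile 84.8) or 0.16 without the highest cells, with the potassium channel KCNJ10 at 82.9 and 12.2 CPM. In oligodendrocyte-like cells KCNJ10 was at 95.3 and 6.24 CPM, and the fatty acid elongase ELOVL1 was at 2664 and 4175 CPM.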
